A study of Solanum lycopersicum with 6 samples.

How the data were processed

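Single-nucleus RNA sequencing was performed on roots of tomato (Solanum lycopersicum, cultivar Moneymaker). Per the labels, the plants were composite plants, in which transgenic roots grow from a wild-type shoot. Their roots carried an mCherry marker under the pRolD promoter and GFP under the promoter of SlPT4, a phosphate transporter gene of tomato. Plants were inoculated with the arbuscular mycorrhizal fungus Rhizophagus irregularis at about 250 spores per plant, or mock-inoculated, watered with a nutrient solution holding 20 µM phosphate, and harvested 6 weeks after inoculation. Each library came from root sections of 10 to 12 plants (about 200 mg), so the spread between libraries is a spread between pools of plants. Nuclei were stained with propidium iodide and sorted before loading. Each treatment has 3 libraries. Replicate 1 of both treatments was made with the 10x Genomics 3′ kit of version 3.1, and replicates 2 and 3 with version 4, so that the kit is a batch balanced over the treatments.

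The deposited files hold whole-number UMI counts per feature and nucleus barcode, with no normalisation, after the barcode filter of the counting software. Per the submitters' processing notes, the tools were Cell Ranger 8.0.1 and STAR. The STAR version, the genome build and the annotation are not given in the sources used here. The count tables hold 34285 features per library, of which 34075 are nuclear genes, 71 mitochondrial, 138 plastid and 1 GFP. Fungal genes and mCherry were not among the features and were not analysed here. The files give feature identifiers without names. The reference table at hand (RefSeq genes of assembly SLM_r2.1) matched 0 of the 34075 nuclear identifiers. Gene symbols are therefore printed only for identifiers on gene lists that paired symbols with identifiers from general knowledge. Neither the files nor the reference table checks these pairs, so each symbol is to be read as the list's name for its identifier, which is a looser rule than printing identifiers alone. Of the other genes, at most 2 identifiers that rose and 2 that fell are printed per comparison.

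Barcodes with fewer than 300 genes, or with over 5% of UMIs on organelle genes, were left out, which kept 55021 of 63853 barcodes. The organelle filter removed between 6.69% and 20.2% of the barcodes of a library, most in the libraries of kit version 4. Doublets were sought with Scrublet, run per library through scanpy 1.11.5. It marked 2 of 63853 barcodes (0.00313%), which is too few for a working caller, so that doublets were in effect not removed. As an alternative, the 8% of barcodes with the highest doublet scores were left out. Pairs of libraries within a treatment differed far beyond sampling noise (chi-square per degree of freedom between 26.9 and 422), and all 6 libraries were kept as separate samples.

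UMI counts were summed over the kept nuclei of each library, since nuclei are not replicates. Treatments were compared with edgeR 4.0.16 (R 4.3.3), using TMM scaling, filterByExpr, a quasi-likelihood test with the kit as a covariate, and Benjamini-Hochberg adjustment at 0.05. A fold change is given as log2 of inoculated over mock. The same test was run on sums within clusters. Clusters were made from log-transformed counts per 10000 of 2000 variable genes, centred within kit, with 30 principal components, 20 nearest neighbours and Leiden clustering (igraph 0.11.9) at resolution 0.8. Left out of the clustering were 122 genes, namely the AM core list and every gene called in the whole-root test with an absolute log2 change of 1 or more. The test ran in each cluster with at least 50 nuclei in every library. A difference between the effect in a cluster and that in all other nuclei was tested as an interaction, with the library as a block. Shares of nuclei per cluster were tested with edgeR on nuclei counts, with the library total as an offset.

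A nucleus with at least 1 PT4 UMI was called PT4-positive. Within each inoculated library, the counts of PT4-positive nuclei were compared with those of PT4-negative nuclei weighted to the same cluster shares, with the library as a block. Shares of nuclei with a UMI were compared by exact two-sided permutation tests over libraries, whose smallest possible p with 3 against 3 is 0.1. Each library's share has an exact (Clopper-Pearson) 95% interval, and a count of 0 allows a share of up to 3 counts of the total. These intervals and limits cover counting error only. For a comparison across depths, nuclei were thinned to 1000 UMIs, which left out 3936 inoculated and 4522 mock nuclei below that number.

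Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on the whole-root fit, with adjustment over the response lists of at least 3 tested genes, and apart from these over the cell-type lists. Camera with an estimated correlation and fry were alternatives. Of 19 lists, 7 were fixed before the data were examined, along with the tests, filters, covariates and most alternatives. The other 12 lists were written once the identifiers had been seen, but before any count was read. Lists that were defined by gene descriptions could not be used, as the files give none. The rule for named genes took the largest changes past the threshold with a mean CPM of at least 5 that moved the same way in all 3 same-numbered libraries, and the members of the lists.

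Alternatives were a replicate block in place of the kit, no covariate, the version 4 libraries alone, DESeq2 1.42.0, no filter on low counts, all deposited barcodes, each library left out in turn, other clusterings, other definitions of positive nuclei and other weights of the negatives. The alternatives without the highest doublet scores, without the nuclei of cluster 13, with 1534 genes left out of the clustering (unadjusted p under 0.05 and an absolute log2 change of at least 0.5), with positive nuclei defined by a UMI of PT4, RAM2, STR or AMT2.2, and with those defined by RAM2, STR or AMT2.2 without a PT4 UMI were chosen after seeing the data.

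The edgeR tests of genes were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds, and those within clusters only in cluster 3. The exact permutation tests and the comparison of cluster 13 with the other nuclei were not tried on simulated counts. Over 21909 simulated genes, the whole-root test recovered 5.0% of 2-fold, 70.0% of 4-fold and 97.5% of 16-fold increases, and 65.0% of 4-fold decreases, with 9 false calls. DESeq2 recovered 27.5% of the 2-fold increases there, with 89 false calls. The test within cluster 3 recovered 35.0% of 2-fold and 95.0% of 4-fold increases over 16135 genes, with 13 false calls. The interaction test of cluster 3 recovered 80.0% of 4-fold increases over 20549 genes, with 18 false calls. The test of PT4-positive nuclei recovered 52.5% of 4-fold increases and 30.0% of 4-fold decreases over 14892 genes, with 5 false calls. In 20 simulated tables of 24 clusters, the share test recovered 9 of 40 clusters changed 8-fold, with 7 false calls, and 31 of 40 changed 32-fold, with 3. Camera with the preset correlation recovered 30 of 30 lists raised 4-fold with 3 false calls, and fry and the estimated correlation recovered as many with 0. Simulated genes were drawn independently of each other, whereas the estimated correlation within real lists reached 0.555 (common symbiosis signalling). The false calls of lists therefore do not carry over to correlated lists.

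Total depth ranged from 23843614 to 47105845 UMIs per library, and the median nucleus held between 2027 and 3024 UMIs.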

Results

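Libraries of single nuclei from tomato roots were compared between plants inoculated with the arbuscular mycorrhizal (AM) fungus Rhizophagus irregularis and mock-inoculated plants, with 3 libraries per treatment. The inoculated libraries held 47105845, 32373338 and 23843614 UMIs in 11368, 10314 and 8137 barcodes (replicates 1 to 3). The mock libraries held 38298739, 38171050 and 39041362 UMIs in 12527, 9114 and 12393 barcodes. After filtering, 25740 nuclei of inoculated and 29281 of mock roots were kept. The mitochondrial share of UMIs lay between 1.53% and 1.66% in the libraries of kit version 3.1 and between 4.28% and 5.37% in those of version 4. Mock replicate 1 stood apart from the other libraries on the main axis of variation (41.2% of the variance). Its correlation with the other libraries in log CPM lay between 0.900 and 0.918, against 0.941 to 0.979 among the remaining libraries. Symbols below are those of the gene lists, whose pairing with identifiers rests on general knowledge and was not checked against a reference.

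The comparison of whole roots asks which genes respond to the fungus. In inoculated roots 112 genes rose and 3 fell among 22257 tested genes (edgeR). Many of the increases were large, with a log2 change above 2 for 97 of the 112 genes and above 4 for 56. The median was 4.03, also with the 7 genes without a mock UMI set at their lower bounds. All 112 were higher in all 3 same-numbered pairs of libraries. Solyc05g055490.3 reached 12.3 ± 3.32 CPM (SD, n = 3) in inoculated roots and had no UMI in mock roots, at least 409-fold higher by the limit of 3 counts over the mock group. Solyc11g008840.3 reached 12.5 ± 6.50 CPM and was at least 366-fold higher by the same limit (adjusted p = 0.0332 and 0.0321, edgeR quasi-likelihood test). Counting intervals of these ratios started lower, at 332 and 297. Among the lower genes, Solyc05g041200.4 fell from 32.8 ± 2.74 to 13.7 ± 1.72 CPM (log2 change -1.32, SE 0.17, adjusted p = 0.0495). Solyc02g077070.3 fell from 33.9 ± 5.91 to 14.3 ± 1.64 CPM (log2 change -1.30, SE 0.15, adjusted p = 0.0381). They were among the 10 leading genes of clusters 16 and 1, whose shares of nuclei are given with the clusters, which was looked up after their values were seen.

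At an unadjusted p under 0.05, 1644 genes differed. The count of higher genes fell to 1 without the 1911 nuclei of cluster 13, to 18 with a replicate block, and to 7, 9, 0 and 0 without inoculated replicate 2, inoculated replicate 3, mock replicate 2 and mock replicate 3 (1526 and 1036 genes at an unadjusted p under 0.05 in the last pair). It rose to 484 with DESeq2, to 259 in the version 4 libraries alone, and to 258 and 268 without inoculated or mock replicate 1, where 110, 62, 71 and 65 genes were lower. With the kit as a covariate, the last pair of settings in effect repeats the comparison of the version 4 libraries alone. All 112 genes kept their sign in each of these settings in which they were tested. As they were picked as higher in these same libraries, this was largely fixed in advance and is no separate evidence.

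The genes best known from arbuscular mycorrhiza formed the AM core list of 9 genes. STR (Solyc01g097430.4), an ABC transporter needed for arbuscule development, was at 4.97 ± 3.34 CPM in inoculated roots and had 1 UMI in mock roots, a ratio of 579 with a counting interval of 103 to 22894. DXS2 (Solyc11g010850.2), at the entry of the plastid isoprenoid pathway, rose from 9.91 ± 2.35 to 36.2 ± 10.4 CPM (log2 change 1.80, SE 0.18). Both passed the test over all genes (adjusted p = 0.0346 and 0.0293, edgeR), and both calls ended without inoculated or mock replicate 2 or 3 (adjusted p between 0.130 and 0.273 for STR and between 0.138 and 0.273 for DXS2). Adjusted over the list alone, 6 of the 9 genes rose. The other 4 were RAM2 (Solyc02g087500.3), an acyltransferase of lipid supply to the fungus, the phosphate transporters PT4 (Solyc06g051850.2) and PT5 (Solyc06g051860.3), and the transcription factor RAM1 (Solyc02g094340.1). Their log2 changes were 5.77, 4.41, 1.44 and 1.71 (SE 0.86, 1.24, 0.49 and 0.31). PT4 averaged 1.88 ± 2.24 CPM in inoculated roots and 0.0541 ± 0.0497 CPM in mock roots. The ammonium transporter AMT2.2 (Solyc08g067080.3), the phytoene synthase PSY3 (Solyc01g005940.4) and the carotenoid cleavage enzyme CCD1B (Solyc01g087260.4) had log2 changes of 3.15, 1.07 and -0.11 and did not pass. With a library left out, the log2 change was lowest without inoculated replicate 1 and highest without mock replicate 3 for PT4 (2.64 to 5.65), STR (7.13 to 10.65) and AMT2.2 (1.93 to 5.17). As the kit term takes up mock replicate 1 there, the lowest values reflect the loss of both version 3.1 libraries, not of that library by itself. The list as a whole was higher by camera (adjusted p = 1.06e-09), with an adjusted p = 0.108 with an estimated correlation, and by fry (adjusted p = 0.0270). The estimated correlation was 0.0150, near the preset 0.01, so the loss of this call does not show that these genes were correlated.

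**Figure D1:**
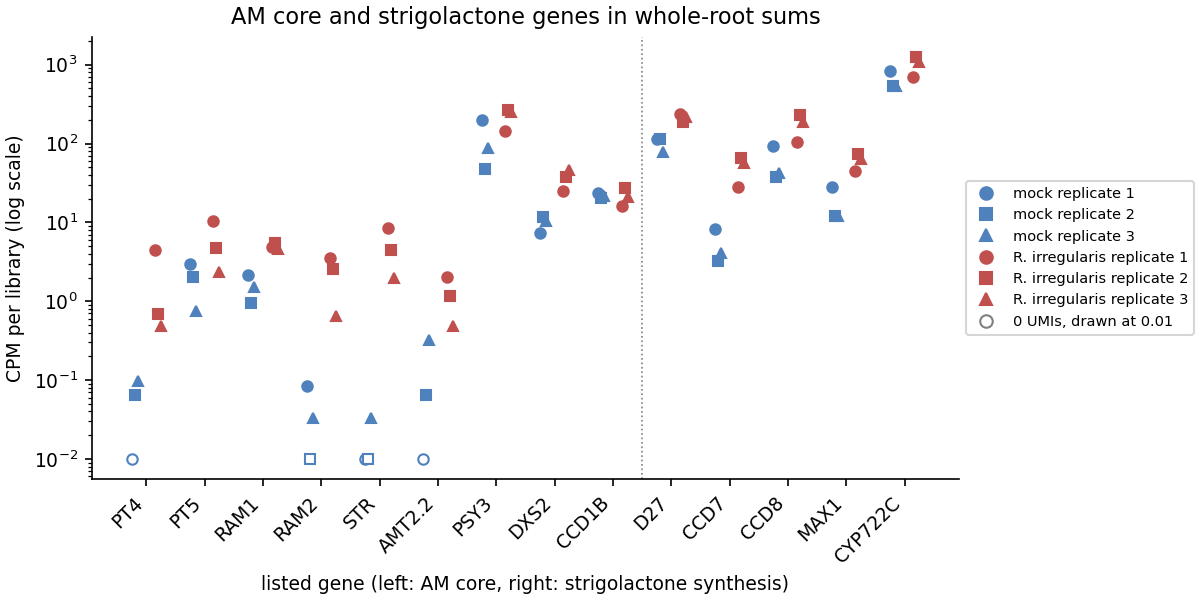
CPM per library (log scale) of the 9 AM core genes, left of the dotted line, and the 5 strigolactone synthesis genes in whole-root sums, with 1 point per library, colour for treatment, shape for replicate and open points at 0.01 CPM for 0 UMIs. CCD7 lies between 28.3 and 66.1 CPM in the inoculated libraries and between 3.20 and 8.17 CPM in the mock libraries, while CCD1B overlaps.

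Genes of strigolactone synthesis, the pathway to the root signals that activate AM fungi, were all positive. CCD7 (Solyc01g090660.3), a carotenoid cleavage dioxygenase of this pathway, rose from 5.14 ± 2.65 to 50.2 ± 19.6 CPM (log2 change 3.26, SE 0.46). MAX1 (Solyc08g062950.4), CCD8 (Solyc08g066650.3) and D27 (Solyc09g065750.3) had log2 changes of 1.83, 1.60 and 1.01 (SE 0.34, 0.42 and 0.23), and these 4 of the 5 genes rose adjusted over the list alone. CYP722C (Solyc02g084930.3), of orobanchol synthesis, was at 0.60 and did not pass. Over all genes 0 of the 5 passed (edgeR, with all but CYP722C at an unadjusted p under 0.05), whereas 4 passed with DESeq2. Camera called the list higher (adjusted p = 1.74e-07), with an adjusted p = 0.120 with an estimated correlation and fry's adjusted p = 0.0360.

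Steroidal glycoalkaloid genes, which make tomatine and its relatives, were positive for all 9 members. GAME17 (Solyc07g043480.1), GAME6 (Solyc07g043460.3), GAME11 (Solyc07g043420.3), GAME1 (Solyc07g043490.1) and GAME12 (Solyc12g006470.2) rose adjusted over the list alone, with log2 changes of 2.09, 1.96, 1.74, 1.13 and 0.82. In the carotenoid list, PDS (Solyc03g123760.3) and ZDS (Solyc01g097810.3), the desaturases of carotene synthesis, rose by that measure (log2 change 0.71 and 0.98), and 13 of 15 tested members were positive. Camera called both lists higher (adjusted p = 1.74e-07 and 1.96e-04), with adjusted p = 0.168 and 0.338 with an estimated correlation. Fry's adjusted p was 0.101 and 0.168. In all, camera with the preset correlation called 4 of 14 response lists, fry 2 and the estimated correlation 0 (3 lists had an unadjusted p under 0.05 there), and leaving out inoculated or mock replicate 1 gave 8. Both of these left-out settings in effect compare the version 4 libraries alone. The carotenoid call ended without inoculated replicate 2 (adjusted p = 0.101, camera).

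The remaining lists did not pass with all libraries. Without inoculated replicate 1, camera called common symbiosis signalling and gibberellin higher (adjusted p = 0.00803 each) and jasmonate and salicylate lower (0.00823 and 0.0282). Without mock replicate 1 it made the same 4 calls (0.00833 for the first 3 lists and 0.0284 for salicylate). With the kit as a covariate, both settings in effect compare the version 4 libraries alone. Their agreement was thus fixed by the design and is no separate evidence. With all libraries, common symbiosis signalling had a median log2 change of 0.38 (adjusted p = 0.126, camera), with CCaMK at 0.56, CYCLOPS at 0.82, LYK10 at 0.38, SYMRK at -0.13 and DELLA at -0.02. SYMRK and DELLA were positive in the version 4 libraries alone. Of 7 tested gibberellin genes, GA20ox4 rose adjusted over the list alone (log2 change 2.94), but the list's median was 0.04 (adjusted p = 0.390). In the salicylate list PR1a2, a pathogenesis-related protein gene, fell by that measure (log2 change -1.32), with a list median of -0.06 (adjusted p = 0.327). Medians were -0.14 for jasmonate (adjusted p = 0.938), -0.32 for ethylene (0.146), 0.14 for flavonoid synthesis (0.867) and -0.08 for 7 reference genes (0.430). Iron uptake had a median of 0.03 and a mean of -0.15 (adjusted p = 0.677, direction down). Sucrose transport and cleavage had a median of -0.06 and a mean of 0.08 (adjusted p = 0.867, down), and nitrogen uptake and assimilation a median of -0.24 and a mean of 0.10 (adjusted p = 0.988, up in camera and down in fry). Only 2 Rubisco small subunit genes were tested, RBCS3A at -1.31 (lower adjusted over the list alone) and RBCS1 at 0.00.

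Cell-type lists were tested beside these. The endodermis list (CASP1 1.19, CASP2 1.32, SCR 0.41 and MYB36 -0.38) and the suberised layer list (median 0.36, 7 of 9 positive) were each higher with an adjusted p = 0.0499 by camera. The endodermis call ended without inoculated replicates 1 and 3 (adjusted p = 0.0533 and 0.174) and without mock replicates 1, 2 and 3 (0.0534, 0.129 and 0.236). The suberised layer call ended without inoculated replicates 1 and 2 (0.0533 and 0.422) and mock replicates 1 and 3 (0.0534 and 0.602). With an estimated correlation the adjusted p was 0.281 and 0.342. Of the exodermis regulators EXO1 was at 0.34 and SCZ at -0.09, and the phloem gene SUT1 at -0.14.

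Clustering asked whether the fungus changed the makeup of the nuclei. The kept nuclei fell into 24 clusters, of which cluster 13 differed in its share. It held 7.13% ± 1.1 of the nuclei of inoculated roots and 0.223% ± 0.111 of those of mock roots (log2 change 5.09, SE 0.44, adjusted p = 0.00552, edgeR), with an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 allows. The lowest inoculated share was 6.38% and the highest mock share 0.351%, and the shares were apart in both kits. Of its 1911 nuclei, 69 came from mock roots, and its median nucleus held 1.66 times the UMIs of its library's median nucleus. All but 2 of the 112 genes that rose in whole roots were higher in cluster 13 than in the other nuclei of the inoculated libraries (edgeR, median log2 difference 3.93). These 112 genes were kept out of the clustering but were called in these same libraries. Without the nuclei of cluster 13 only 1 gene was higher in whole roots. Their higher level in cluster 13 was thus largely fixed by how they were picked, and is no separate evidence.

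The other clusters did not pass. Cluster 1 held 6.88% ± 2.93 of inoculated and 16.9% ± 1.85 of mock nuclei (adjusted p = 0.166), cluster 16 held 0.668% ± 0.147 and 2.48% ± 1.46 (adjusted p = 0.166), and cluster 18 held 0.719% ± 0.401 and 2.00% ± 1.60 (adjusted p = 0.166). Cluster 19 held 1.88% ± 0.441 and 0.927% ± 0.254 (adjusted p = 0.216). Cluster 22, suberised-layer-like with 8 of 9 markers higher, held 0.526% ± 0.410 and 0.256% ± 0.0938 (adjusted p = 0.591). Cluster 23, endodermis-like with 3 of 4 markers higher, held 0.378% ± 0.0889 and 0.215% ± 0.0661 (adjusted p = 0.360). Mock replicate 1 had 22.6% of its nuclei in cluster 8 and 6.12% in cluster 17, against at most 0.986% and 0.555% in the other libraries. Clusters 6, 7, 9, 10 and 12 each held between 0.163% and 0.821% of mock replicate 1. They each held between 6.42% and 9.81% of inoculated replicate 1, and between 1.19% and 11.6% of the version 4 libraries. Cluster 21 had 273 of its 286 nuclei from inoculated replicate 1 (2.59% of that library, at most 0.0532% of the others, adjusted p = 0.591). Its median nucleus held 0.235 times the UMIs of its library's median nucleus, and the 273 nuclei together had 5 PT4, 5 RAM1 and 9 STR UMIs. The call for cluster 13 ended without inoculated replicate 3 (log2 change 5.10, SE 0.55, adjusted p = 0.0530) and without mock replicate 3 (4.94, SE 0.60, 0.0731), over a range of 6.09e-04 to 0.0731 in its alternatives, and without mock replicate 2 there were 2 calls. At resolution 0.4, and with the wider set of genes left out of the clustering, 0 clusters were called by edgeR (4 and 0 at an unadjusted p under 0.05, no other tool run).

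**Figure D2:**
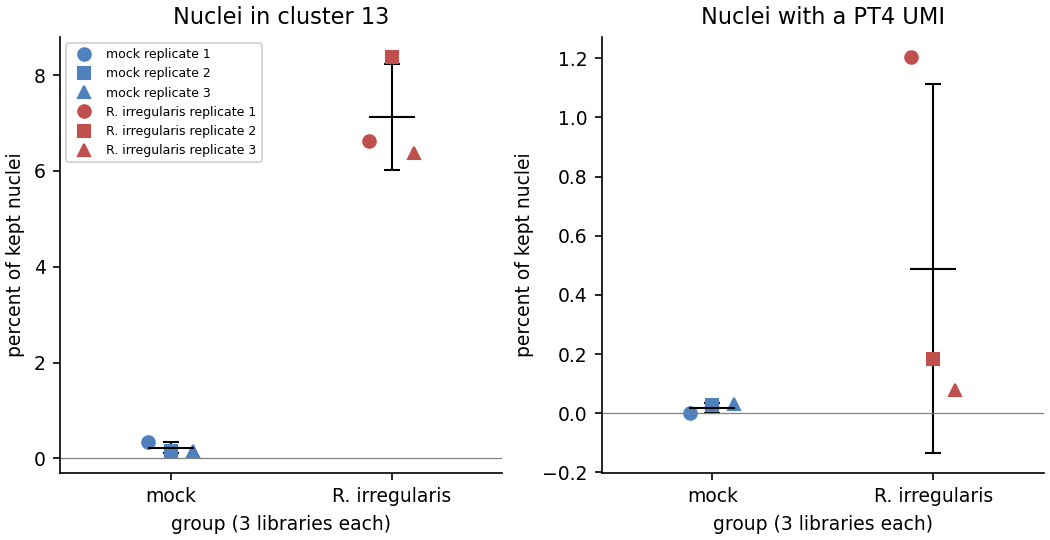
Percent of kept nuclei in cluster 13 (left) and with a PT4 UMI (right) in the 3 mock and 3 inoculated libraries, with 1 point per library and black bars for the mean and SD of each treatment. Cluster 13 holds 6.38% or more of each inoculated library and 0.351% or less of each mock library, and inoculated replicate 1 has the highest PT4 share, at 1.21%.

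Changes within clusters ask which nuclei respond. Of 13 clusters with enough nuclei, clusters 2 and 3 gave 95.4% of the 173 calls of higher genes, with 57 and 108, and 4 and 13 lower. Cluster 13 was not tested, with 41, 12 and 16 nuclei in mock replicates 1, 2 and 3. The genes higher in whole roots had median log2 changes of 2.65 and 3.03 in clusters 2 and 3. In the clusters without calls these medians ran from 0.811 to 2.19, so a lack of calls does not show a lack of response. In cluster 2, Solyc02g069420.4 (25.2 ± 4.71 CPM) and Solyc11g007280.3 (11.5 ± 6.20 CPM) had no mock UMI and were at least 55.2-fold and 24.8-fold higher (limit of 3 counts over the group). In cluster 3, Solyc04g072480.3 (10.2 ± 1.38 CPM) and Solyc03g112110.1 (9.36 ± 2.98 CPM) were at least 33.6-fold and 30.7-fold higher. Counting intervals of these ratios started lower, at 44.4 and 19.7 in cluster 2 and at 26.9 and 24.5 in cluster 3. Of these genes, Solyc02g069420.4, Solyc11g007280.3 and Solyc04g072480.3 were also among the 10 leading genes of cluster 13. Solyc12g044330.2 and Solyc08g068730.1 fell in cluster 2 (log2 change -1.56 and -1.48), and Solyc01g150176.1 and Solyc07g052980.3 in cluster 3 (-2.24 and -1.92). The median change of the higher genes was 2.55 in cluster 2 and 2.04 in cluster 3.

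Listed genes called in cluster 3 (edgeR, adjusted p between 0.00203 and 0.0357) were CCD7, GAME6, GAME11, MAX1, DXS2, PSY3, PDS, CYCLOPS, D27, ZDS and GAME12. Their log2 changes were 5.29, 4.04, 3.83, 3.08, 2.40, 1.94, 1.44, 1.39, 1.38, 1.37 and 1.26. Of these, CCD7, GAME6, GAME11, MAX1, D27, ZDS and GAME12 were among the genes that made the clusters. Clusters 2 and 3, whose nuclei come from the same 6 libraries, shared 23 higher genes among 14540 genes tested in both. Cluster 5 had 6 higher genes, cluster 11 had 1, and cluster 15 had 1 higher and 1 lower. The other 8 clusters had 0 calls in edgeR, with 165 to 839 genes at an unadjusted p under 0.05 and 0 to 29 higher genes with DESeq2.

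The summed counts of higher and lower genes were 63 and 3 with a replicate block, 560 and 140 with DESeq2, and 346 and 69 at resolution 0.4. Without inoculated replicates 1, 2 and 3 the higher genes numbered 443, 60 and 100, and without mock replicates 1, 2 and 3 they numbered 462, 66 and 23 (lower genes 353, 2, 11, 333, 3 and 1). The settings without either replicate 1 in effect compare the version 4 libraries alone.

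**Figure D3:**
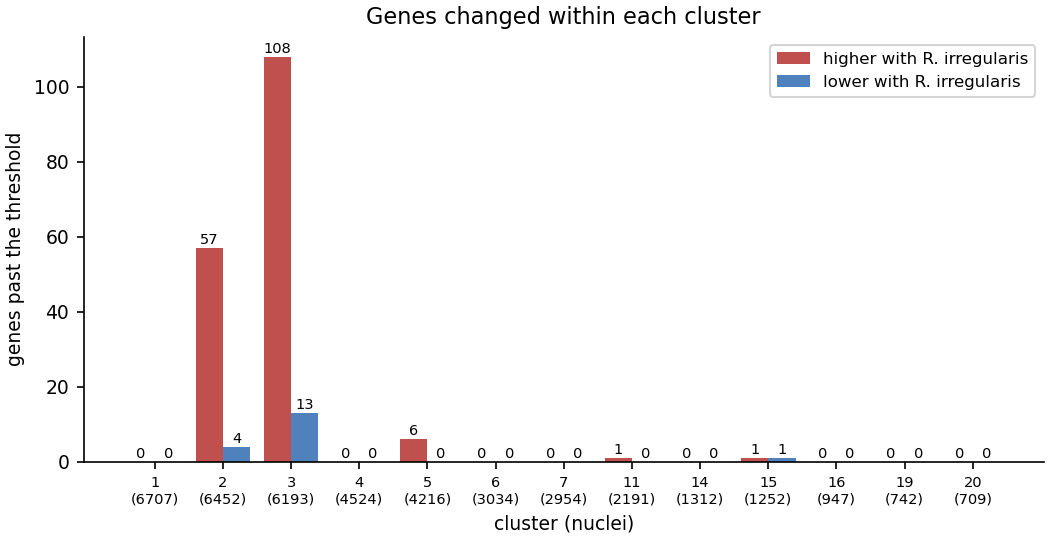
Number of genes higher (red bars) and lower (blue bars) with the fungus within each of the 13 tested clusters, with the number of nuclei under each cluster number. Cluster 3 has 108 higher and 13 lower genes and cluster 2 has 57 and 4, and no other cluster has more than 6 of either.

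Whether an effect differed between a cluster and all other nuclei was tested as an interaction. It passed for 163 genes over the 13 clusters, of which 86 were in cluster 1, 39 in cluster 16, 18 in cluster 20 and 13 in cluster 14. Other splits of the libraries into equal groups gave as many as 329 and 649 genes, as described below. In cluster 1 the effect was smaller than elsewhere for all but 3 of the genes. They included the strigolactone genes CCD7, CCD8, MAX1 and D27, along with DXS2, PSY3, ZDS and GA3ox1, a gibberellin oxidase. In clusters 2 and 3 the test called 0 genes (edgeR, no other tool run), with 899 and 841 at an unadjusted p under 0.05, so the effects there were not shown to differ from those in other nuclei. The count was 710 without mock replicate 1, 90 without mock replicate 3, and 107 when the clustering used all variable genes.

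Nuclei with a PT4 UMI were counted in each library. They made up in 127 of 10534 nuclei of inoculated replicate 1 (1.21%, exact 95% interval 1.01% to 1.43%), 16 of 8715 in replicate 2 (0.184%, 0.105% to 0.298%) and 5 of 6491 in replicate 3 (0.0770%, 0.0250% to 0.180%). Mock nuclei had 0, 2 and 3, with exact upper limits of 0.0316%, 0.0961% and 0.0870%. The interval of inoculated replicate 3 overlapped those of the mock libraries, and the intervals of inoculated replicates 1 and 2 lay above them. Mean shares were 0.489% ± 0.623 and 0.0188% ± 0.0164 (n = 3 each), with an exact permutation p of 0.1 (two-sided), the smallest possible. The difference of 0.470 percentage points was 0.112 without inoculated replicate 1, and 0.151 after thinning each nucleus to 1000 UMIs. Of the positive nuclei, 41 of 127, 7 of 16 and 3 of 5 lay in cluster 13.

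A GFP reporter under the PT4 promoter was carried by all roots. With version 4, GFP was at 63.0 and 51.0 CPM in inoculated replicates 2 and 3 and at 32.9 and 38.9 CPM in mock replicates 2 and 3. With version 3.1 it was at 108 CPM in inoculated and 189 CPM in mock replicate 1. Over all libraries, GFP UMIs occurred in 17.3% ± 9.09 of inoculated and 16.5% ± 12.4 of mock nuclei (exact permutation p = 0.8), at 74.0 ± 30.0 and 87.0 ± 88.6 CPM (exact permutation p = 1). Within the inoculated libraries, 58.3%, 43.8% and 20.0% of the PT4-positive nuclei of replicates 1, 2 and 3 had a GFP UMI, against 27.3%, 13.6% and 10.6% of the PT4-negative nuclei. The 20.0% is 1 of 5 nuclei. The positive nuclei were deeper, with median UMI counts of 4845 against 2985 in replicate 1, and scaled to UMIs GFP was at 314, 170 and 576 CPM in positive and 104, 62.8 and 50.6 CPM in negative nuclei.

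The comparison of PT4-positive with other nuclei of the same libraries asks what these nuclei express. Of the other 8 AM core genes, 5 were higher in them (edgeR): RAM2 with a log2 change of 3.65 (SE 0.54), AMT2.2 3.58 (0.54), PT5 3.56 (0.58), STR 3.02 (0.52) and RAM1 2.36 (0.55). Of the other 3, DXS2 was lower, at -2.42 (0.65), and PSY3 and CCD1B were at -1.18 and -0.79 and did not pass. GA3ox1 was lower, at -2.77 (0.73). The 5 strigolactone genes were all negative, from -1.86 for CCD8 (adjusted p = 0.0615) to -0.33 for CCD7, and 0 passed in edgeR, where 3 had an unadjusted p under 0.05, and 0 in DESeq2. Over all genes 134 rose and 16 fell among 15396 tested, with 679 at an unadjusted p under 0.05. Solyc05g048780.1 and Solyc10g008530.1 rose by 5.99 and 5.48 on the log2 scale, from 20 and 24 UMIs in the positive nuclei. Solyc01g057707.1 and Solyc03g119470.2 had no UMI there and were at least 6.24-fold and 3.13-fold lower (limit of 3 counts over the group). Counting intervals of their ratios to the other nuclei were wider, reaching up to 0.198 and 0.397.

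Camera called the AM core list higher (adjusted p = 1.59e-05), strigolactone synthesis lower (5.25e-08), the carotenoid list lower (0.0153) and iron uptake higher (0.0269), each with an adjusted p = 0.375 with an estimated correlation. Fry called AM core (adjusted p = 0.00372) and iron uptake (0.0496), and not strigolactone synthesis (0.245) or carotenoids (0.175). The counts rest on inoculated replicate 1, without which 15 genes were higher and 0 lower (353 at an unadjusted p under 0.05). Without inoculated replicate 2, 93 were higher and 3 lower, and with DESeq2 84 and 4. Other definitions of positive nuclei gave larger counts, such as 153 higher and 62 lower with at least 2 PT4 UMIs. With RAM2, STR or AMT2.2 but no PT4 UMI, 516 were higher and 247 lower. Where nuclei with UMIs of at least 2 AM core genes were taken as positive, a definition that 2.29% of mock nuclei also met, the 5 strigolactone genes and GA3ox1 were positive instead, and CCD7 was also positive against unweighted negatives (log2 change 1.22).

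**Figure D4:**
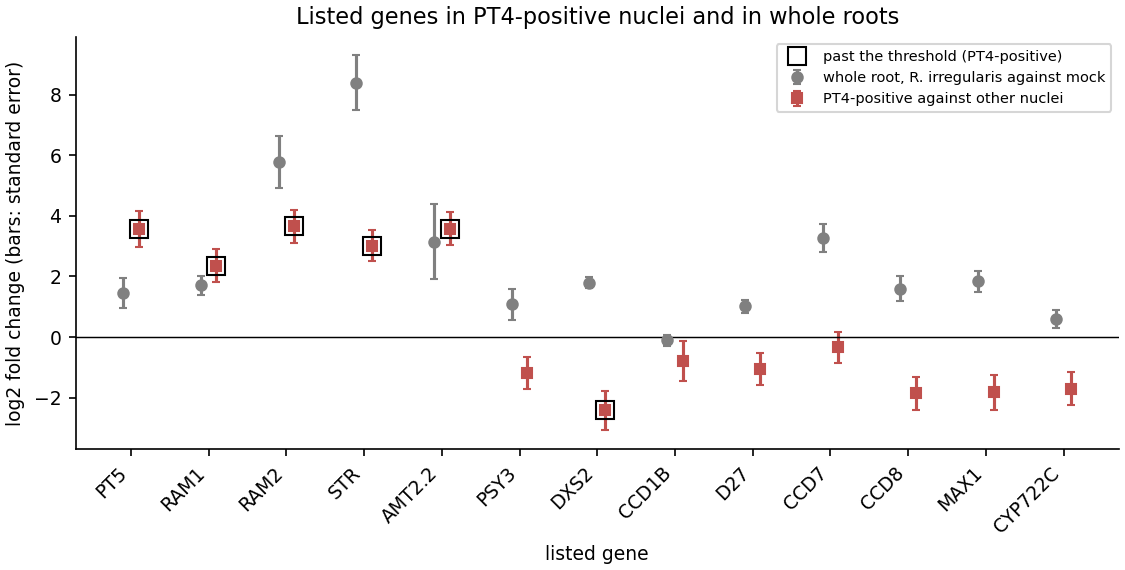
Log2 fold change of the listed AM core and strigolactone genes in PT4-positive nuclei against other nuclei of the inoculated libraries (red squares) and in whole inoculated against mock roots (grey points), with standard errors as bars and black frames for genes past the threshold in PT4-positive nuclei. RAM2, STR, AMT2.2, PT5 and RAM1 are positive in both, and CCD8, at 1.60 in whole roots, is at -1.86 in PT4-positive nuclei.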

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

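The count of library splits given here was chosen after the result was seen, and the interaction test itself was not. The effect of the fungus differed between a cluster and the other nuclei, by the edgeR interaction test, for 86 genes in cluster 1, 39 in cluster 16, 18 in cluster 20, 13 in cluster 14, 3 in cluster 19, and 2 each in clusters 4 and 15. The listed genes in cluster 1 all had a lower effect there than in the other nuclei, which include cluster 13. A weaker response of cluster 1 nuclei therefore cannot be told apart from the presence of cluster 13 among the others. The log2 difference was -4.35 for GA3ox1, -2.46 for CCD7, -2.02 for CCD8, -1.82 for MAX1, -1.78 for DXS2, -1.74 for PSY3, -0.95 for D27 and -0.86 for ZDS (adjusted p between 0.00129 and 0.0194). GAME12, of glycoalkaloid synthesis, had a higher effect in cluster 14 than elsewhere, by 1.35 (adjusted p = 0.0412).

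Of the 10 splits of the 6 libraries into groups of 3, 3 gave at least the 163 genes of the treatments. The highest other split, inoculated replicate 1 with mock replicates 2 and 3 against the rest, gave 649. It sets the treatments apart within each kit, with opposite signs in the kits, so it is not free of the treatment. A treatment difference that runs in opposite directions in the kits cannot be told apart here from a structure of the samples apart from the treatment. The 10 splits are too few for a share under 0.05. The count was 710 without mock replicate 1 and 90 without mock replicate 3.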

How the results depend on the processing

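The alternatives without cluster 13, without the highest doublet scores, with the wider exclusion, and with RAM2, STR or AMT2.2 UMIs in the definition of positive nuclei were chosen after seeing the data. The causes of the changes below were not tested. Left-out libraries and the version 4 libraries alone have fewer samples, yet some counts rose there. With the kit as a covariate, leaving out either replicate 1 in effect repeats the version 4 comparison, so those rises are not separate results. Higher genes in whole roots numbered 259 in the version 4 libraries alone, against 112 with all libraries.

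With a replicate block, whole-root counts were 18 higher and 0 lower (edgeR, 1228 genes at an unadjusted p under 0.05, and DESeq2 was run without the block), and within-cluster counts 63 and 3. Correlations of same-numbered deviations from the treatment means were 0.146, -0.03 and 0.159 for replicates 1, 2 and 3. As mock replicate 1 stood apart and weighs on the mock mean, these values do not show that the libraries were unpaired. For PT4-positive nuclei, no replicate block gave 52 and 1.

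Whole-root counts of higher and lower genes were 484 and 110 with DESeq2, 259 and 62 in the version 4 libraries alone, and 1 and 0 without cluster 13 (1416 genes at an unadjusted p under 0.05). Lower genes numbered 1 with no covariate and 6 with no filter. Within clusters the counts were 560 and 140 with DESeq2, 346 and 69 at resolution 0.4, and 1018 and 350 with the wider exclusion, and 36 were lower without the highest doublet scores. The interaction count was 107 with all variable genes in the clustering. The share test called 0 clusters at resolution 0.4 and 0 with the wider exclusion. Of the gene lists, 0 were called with an estimated correlation and 2 with fry.

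For PT4-positive nuclei the counts were 257 and 176 with at least 2 AM core genes, 497 and 224 with a PT4, RAM2, STR or AMT2.2 UMI, 516 and 247 with RAM2, STR or AMT2.2 but no PT4 UMI, and 84 and 4 with DESeq2. Unweighted negatives gave 245 higher genes, and at least 2 PT4 UMIs gave 62 lower genes.

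With a library left out, whole-root counts ranged from 0 to 268 higher and 0 to 71 lower, within-cluster counts from 23 to 462 and 1 to 353, and interactions from 90 to 710. Clusters differing in share ranged from 0 to 2, lists from 3 to 8, and genes of PT4-positive nuclei from 15 to 104 higher and 0 to 22 lower. The PT4 share difference ranged from 0.112 to 0.676 percentage points.

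In whole roots CCD1B, DELLA and SYMRK, none past the threshold, turned to 0.031, 0.34 and 0.12 in the version 4 libraries alone, and ranged from -0.24 to 0.029, -0.16 to 0.34 and -0.24 to 0.12 with a library left out. In PT4-positive nuclei CCD7 turned to 0.79 with at least 2 AM core genes, 1.22 with unweighted negatives, 0.71 with any of PT4, RAM2, STR or AMT2.2, and 0.94 with the last 3 and no PT4 UMI. With at least 2 AM core genes MAX1 was 0.94, CCD8 0.83, D27 0.79, CYP722C 0.45, GA3ox1 0.37 and Solyc03g119470.2 0.20. Solyc03g119470.2 was also 1.05 with any of PT4, RAM2, STR or AMT2.2 and 1.59 without PT4 UMIs, where GA3ox1 was 0.12 and Solyc01g057707.1 0.24. PSY3 was 0.12 with unweighted negatives. Over the settings of single genes in whole roots, 382 values kept their direction and side of the threshold, 30 became calls, 41 lost a call and 9 changed sign. Within clusters 2 and 3, 87 kept both and 65 lost a call, and in PT4-positive nuclei 102 kept both, 8 became calls, 28 lost a call and 15 changed sign.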

Other observations

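The tests of kit, doublets, wider exclusion, depth and evenly spread RNA, the bootstrap bounds, and the counts of splits other than that of the gene lists, were chosen only after the result was seen. In cluster 13, UMIs of PT4, RAM2, STR or AMT2.2 were in 13.1%, 5.75% and 3.38% of the nuclei of inoculated replicates 1, 2 and 3. They were in 0 of 41, 12 and 16 nuclei of the mock replicates, with exact 95% upper limits of 8.60%, 26.5% and 20.6%. These intervals were apart in replicate 1 (inoculated lower limit 10.6%) and overlapped in replicates 2 and 3. DXS2 UMIs were in 26.0%, 34.2% and 38.9% of the cluster's inoculated nuclei (replicates 1 to 3) and in 41.5%, 25% and 75% of its mock nuclei (exact permutation p = 0.5). CCD7 was at 174, 303 and 337 CPM in cluster 13 of inoculated replicates 1, 2 and 3, and at 511, 110 and 227 CPM in that of the mock replicates.

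Cluster 13 was nearly absent from mock libraries. The lowest inoculated share, 6.38%, lay above the highest mock share, 0.351%, in both kits, which argues against the kit as its cause. With the wider set of responding genes left out of the clustering, 85.1% of its nuclei joined 1 cluster that held between 9.48% and 17.5% of every library. That set held all 10 leading genes of the cluster and was picked by treatment, so this joining decides nothing. At resolution 0.4, without the wider exclusion, 77.9% of the nuclei of cluster 13 also joined 1 cluster. That cluster held between 9.09% and 19.7% of every library, mock libraries included. A coarser clustering can also join nuclei of separate types, so the question stays open. For cluster 13, nuclei of a shared type set apart by responding genes cannot be told apart from a type that forms with the fungus. Doublets stay open, since the caller did not work, although 6.28% of its nuclei were among the highest doublet scores against 7.78% of all kept nuclei, and without these 90.3% of the rest stayed in 1 cluster, with at least 6.11% of each inoculated and at most 0.289% of each mock library.

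PT4 UMIs were most frequent in inoculated replicate 1. After thinning to 1000 UMIs its share had a lower bound of 0.253%, above the upper bounds of replicates 2 and 3 (0.119% and 0.170%), which argues against depth. Within it, the thinned share in cluster 13 had a lower bound of 1.09%, above the upper bound of 0.370% in its other nuclei, which argues against free RNA spread evenly over the nuclei of that library. In replicates 2 and 3 the thinned intervals overlapped, with 2 positive nuclei in cluster 13 of each, while without thinning they were apart (lower bounds of 0.386% and 0.150% in cluster 13, upper bounds of 0.214% and 0.119% in the other nuclei). The kit cannot be told apart from the replicate, as 1 inoculated library was made with version 3.1, and a difference in colonisation between the pools of plants, which was not tested, may also be at work.

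The genes higher within clusters 2 and 3 could come from RNA set free by other nuclei. In cluster 3 the median ratio of their CPM to that in the other nuclei was 1.22, 1.09 and 1.18 in inoculated replicates 1, 2 and 3, with lower bounds of 1.03, 0.937 and 0.975 (95% bootstrap intervals over the genes), and 51 of the 108 genes were above 1 in all 3. In cluster 2 it was 1.42, 0.821 and 1.13, with 17 of 57 genes above 1 in all 3. Free RNA alone would stay below 1 if it had the makeup of the other nuclei, and as the bounds reach below 1 and that makeup was not measured, free RNA and a response of these nuclei cannot be told apart in either cluster.

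As a hypothesis, strigolactone genes may be lower in nuclei of an advanced symbiotic state, marked by PT4 UMIs or by UMIs of other AM genes. In nuclei with a RAM2, STR or AMT2.2 UMI and no PT4 UMI, 4 of the 5 genes were negative and CCD7 was higher (log2 change 0.94), and fry, a rotation test fitted across all genes with limma, gave p = 0.193 (adjusted p = 0.549, no exact permutation test was run). Camera called the list lower there (adjusted p = 0.0416), with an adjusted p = 0.637 with an estimated correlation. Where nuclei with UMIs of at least 2 AM core genes were taken as positive, all 5 genes were positive (log2 changes between 0.45 and 0.94). This would go against the hypothesis only if that definition marks such a state. It also counts DXS2, which was lower in PT4-positive nuclei, and PSY3 and CCD1B. UMIs of DXS2, PSY3 and CCD1B were in 5.26%, 17.8% and 6.22% of inoculated and 1.96%, 11.7% and 6.43% of mock nuclei. The definition was met by 5.93% of inoculated and 2.29% of mock nuclei. In inoculated replicates 1 to 3, 38.9%, 54.0% and 52.6% of the nuclei so defined lay in cluster 13. Whether it marks such a state was not tested. The hypothesis stays open.

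The 10 splits of the 6 libraries, and the 4 swaps for PT4-positive nuclei, are too few for a share under 0.05. The whole-root comparison gave 115 genes and the highest other split 0, and 1 of 10 splits gave as many. Within clusters the values were 191 and 51 (1 of 10), for shares 1 and 0 clusters (1 of 10), for PT4-positive nuclei 150 and 107 genes (1 of 4), and for gene lists 4 and 6 (3 of 10). The split with 6 lists set inoculated replicates 1 and 2 with mock replicate 1 against the rest.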
